A study of Mus musculus with 36 samples.

How the data were processed

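Total RNA from kidney cortex of male ApoE knockout mice was depleted of ribosomal RNA and made into directional libraries from 200 ng of input per the labels' protocols. The 36 libraries fall into 6 groups of 6, taken from the sample labels: nondiabetic or diabetic mice, each given vehicle, lipoxin A4 (LXA4) or benzo-LXA4. Replicates are numbered 1 to 6 in the labels, which do not say that each is a separate mouse, so every p-value here measures the spread between these samples, which may be in part technical.

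The deposited values are raw counts per gene in 1 table of 36 columns. Per the submitters' processing notes, base calls were converted with bcl2fastq 2.17.1.14, reads were aligned with STAR and counted per gene with featureCounts, and the genome build was GRCm38. The versions of STAR and featureCounts, the annotation release, the strand setting of the counting and the handling of reads with several matches are not given in the sources used here. The values are whole numbers that sum to a different total in each library. The deposited table had 15,730 genes, the lowest of which had 370 counts over all libraries, so genes with fewer counts are not in it. No 2 libraries held identical counts, and the highest correlation between any pair was 0.9938, so all 36 were treated as separate samples. The column codes were matched to the labels by reading D as diabetic and C as nondiabetic, E as ethanol vehicle, L as LXA4 and BL as benzo-LXA4, with the replicate number at the end, and 0 columns were left unmatched. Gene symbols are those of the deposited table, and 15,692 of the Ensembl gene IDs were found in GENCODE M21, an annotation of GRCm38, from which coordinates, transcript lengths and GC content were taken. Of the genes, 13,989 are protein coding there. Coordinates are counted from 1.

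Total counts per library ran from 8,896,193 to 43,305,005. Depth enters through the count model, in which shallow libraries carry less weight for genes with few counts, and counts were not thinned. CPM values are counts relative to the TMM-scaled library total and are given as mean ± SD over the 6 libraries of a group. The 95% intervals of fold changes come from the fitted spread between libraries.

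The design of each test, the gene lists, the rule for naming genes and the alternatives were written before the data were examined. Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors and the low-count filter of edgeR for the 6 groups, which kept 15,726 genes. All 36 libraries entered a single fit, so that all groups shared one estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, and the threshold was 0.05 with no minimum fold. Comparisons were diabetic with nondiabetic vehicle mice, each compound with vehicle in diabetic and in nondiabetic mice, the compounds with each other within each state, the interaction of each compound with diabetes, and treated diabetic mice with nondiabetic vehicle mice. The share of diabetes-changed genes that moved the opposite way under each compound was set beside 20 simulated groups without any treatment effect compared with the same vehicle libraries, and beside all 20 ways to split the 6 diabetic vehicle libraries between the comparisons.

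There were 39 fixed gene lists. They cover immediate early genes, genes often described as EGR1 targets, extracellular matrix and fibrosis, tubular injury, cytokines with NF-kB targets, myeloid cells, T, NK and B cells, the interferon response, complement and coagulation, TGF-beta and BMP signalling, the renin-angiotensin system, and lipoxin and eicosanoid enzymes and receptors. Further lists hold markers of proximal tubule, loop of Henle and distal convoluted tubule, collecting duct, podocytes, endothelium, smooth muscle with pericytes and juxtaglomerular cells, erythroid cells, adipose tissue, liver and pancreas, and adrenal gland. The others are fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, gluconeogenesis, glycolysis, glucose-responsive genes, oxidative phosphorylation, mitochondrial mRNAs, ribosomal proteins, NRF2 targets, the unfolded protein response, cell cycle, circadian clock, glucocorticoid-responsive, male-biased, female-biased and aryl hydrocarbon receptor genes. A list was tested when at least 5 members were measured, which left out only the adrenal list. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. Calls were repeated with an estimated correlation and with fry, whose p tests whether members move on balance one way. Members that passed are also counted with p-values adjusted over the list alone. Lists of p53 targets, urothelium, inner medulla, brown fat and ribosomal or small structural RNA genes were added after the data were examined.

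Genes were named by a fixed rule. It takes Apoe, Egr1, Egr2, Egr3, Nab1 and Nab2 in every comparison, of which Egr2 and Egr3 were not among the genes measured. It then takes the 10 largest rises and 10 largest falls among genes that passed with a mean of at least 5 CPM in either group, leaving out predicted names. From each list it takes up to 4 passing members by smallest p. Where nothing passed, and for interactions and compound comparisons, it takes the 5 genes with the smallest p. A few genes that the rule names are not reported here.

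Alternatives were RLE size factors, no filter, a filter at a mean of 5 CPM, and the Wald test of DESeq2 1.42.0. Others were voom with sample quality weights of limma, only the groups compared in the fit, and the replicate number as a block. Each library of the groups compared was also left out in turn, while libraries of the other groups stayed in the fit. A further alternative, chosen after seeing the data, left out 2 libraries, nondiabetic vehicle replicate 3 and diabetic LXA4 replicate 6. To read corrections, the mean change of a set of genes with the correction was divided by that without it in the same libraries, with a 95% interval from a jackknife over libraries. For each comparison 100 splits of the libraries, the real one included, were refitted. The scripts were tested on simulated data drawn from the real means and depths. In 3 simulations of 15,726 genes, the LXA4 comparison in diabetic mice recovered 62.2% of genes changed 1.5-fold, 81.6% at 2-fold and 98.0% at 4-fold, with 6.67 false calls per simulation. The diabetes comparison recovered 56.7%, 76.1% and 98.0% at the same folds, with 7 false calls. In 10 simulations without any change, camera called 2 of 380 lists tested. All these simulations drew each gene independently, so they could not show list calls that come from correlation between genes. In other splits of the real libraries, camera called a median of 11 lists for diabetes and 6 for LXA4 in diabetic mice. Its p-values at the preset correlation are therefore likely too small for these libraries. By how much is not known, since splits that mix the groups unevenly keep part of any real difference.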

Results

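Gene expression was measured in the kidney cortex of male mice without functional apolipoprotein E (ApoE−/−, C57BL/6 background), a strain prone to atherosclerosis. Per the labels, diabetes was induced at 6 weeks of age with streptozotocin, a toxin of pancreatic beta cells, in 5 daily doses of 55 mg/kg. Diabetic and nondiabetic mice received ethanol vehicle (0.1%), lipoxin A4 (LXA4, 5 µg/kg), a lipid mediator made from arachidonic acid during the resolution of inflammation, or benzo-LXA4 (1.7 µg/kg), a synthetic analog with a fused benzene ring, 2 times a week. The labels describe an intervention design with treatment in weeks 10 to 16, without saying outright that these libraries come from it. Each of the 6 groups had 6 libraries. Total counts per library ran from 10,086,698 to 32,657,959 in nondiabetic vehicle mice, from 27,170,619 to 43,305,005 with LXA4 and from 22,222,844 to 29,998,197 with benzo-LXA4. In diabetic mice they ran from 18,009,386 to 33,541,143 with vehicle, from 8,896,193 to 35,906,294 with LXA4 and from 23,861,061 to 31,447,742 with benzo-LXA4. Genes for ribosomal and small structural RNAs took 17.6% of the counts of nondiabetic vehicle replicate 3 and 56.8% of those of diabetic LXA4 replicate 6, the shallowest libraries of the series, and at most 6.80% in the other 34. The number of genes called is therefore also given without this pair of libraries, an alternative chosen after seeing the data. In the comparisons where it is not given, it was 0 with and without them.

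**Figure D1:**
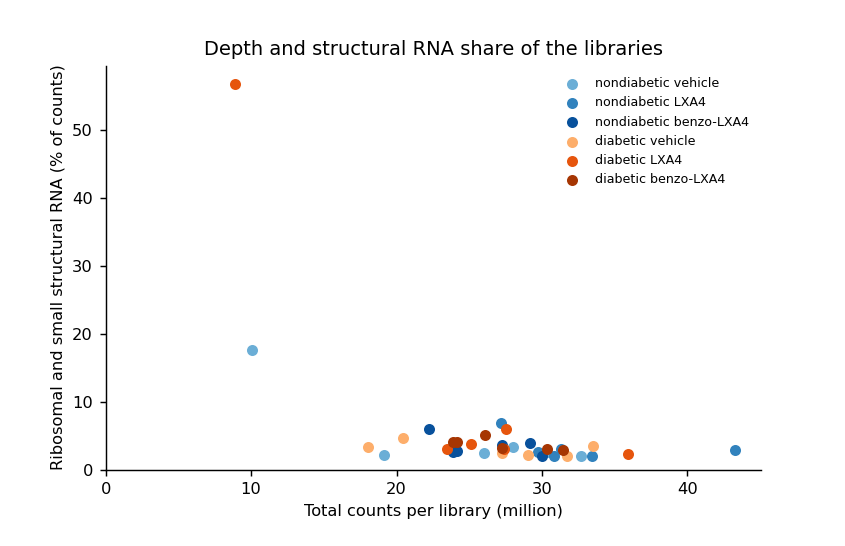
Total counts per library (horizontal axis) against the percentage of counts in ribosomal and small structural RNA genes (vertical axis), 1 point per library, coloured by group. The points at 17.6% and 56.8% are nondiabetic vehicle replicate 3 and diabetic LXA4 replicate 6, and the other 34 libraries lie at or under 6.80%.

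Apoe, the gene disrupted in all of these mice, was still counted at a low and similar level in every group. Counts cover the whole gene (ENSMUSG00000002985, chromosome 7, 19,696,109 to 19,699,188 on GRCm38), so reads from exons outside the disrupted part are included, and no wild-type library was in the series for comparison. With vehicle, Apoe stood at 2.15 ± 0.462 CPM (SD, n = 6) in nondiabetic and 2.14 ± 0.44 CPM in diabetic mice. With LXA4 it stood at 2.36 ± 0.416 and 2.65 ± 0.284 CPM, and with benzo-LXA4 at 2.58 ± 0.681 and 2.27 ± 0.373 CPM, in nondiabetic and diabetic mice. The log2 difference of diabetic from nondiabetic vehicle mice was 0.01 with a 95% interval of −0.34 to 0.35 (adjusted p = 0.993).

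The first question is how the cortex of diabetic mice differs from that of nondiabetic mice under vehicle. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, rose from 4.09 ± 1.35 to 38.6 ± 8.11 CPM (SD, n = 6 per group), a log2 change of 3.22 (SE 0.255, adjusted p = 9.72e-11). Eda2r, a receptor of the TNF receptor family, rose from 0.697 ± 0.12 to 9.95 ± 1.52 CPM (log2 3.78, adjusted p = 8.9e-12). Trp53cor1, a long noncoding RNA encoded next to Cdkn1a, rose from 0.557 ± 0.197 to 5.69 ± 1.19 CPM (log2 3.26, adjusted p = 8.9e-12). Dscaml1, a cell adhesion molecule of the immunoglobulin superfamily, rose from 4.58 ± 1.23 to 36 ± 16.3 CPM (log2 2.95, adjusted p = 5.99e-10). Kcnip4, a potassium channel interacting protein, rose by 2.55 (adjusted p = 9.72e-11) and Kynu, the tryptophan-catabolic enzyme kynureninase, by 2.44 (adjusted p = 3.15e-04). Cyp2d12, a cytochrome P450 gene, fell from 116 ± 53.6 to 30.8 ± 12.1 CPM (log2 −1.93, adjusted p = 2.63e-04). In each of these 7 genes 6 of 6 diabetic libraries lay on the side of the change from the nondiabetic mean. Cdkn1a (ENSMUSG00000023067) lies on chromosome 17 at 29,090,976 to 29,100,727 on GRCm38, Trp53cor1 (ENSMUSG00000085912) on the same chromosome at 29,057,430 to 29,079,179, and Eda2r (ENSMUSG00000034457) on chromosome X at 97,333,840 to 97,377,216.

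**Figure D2:**
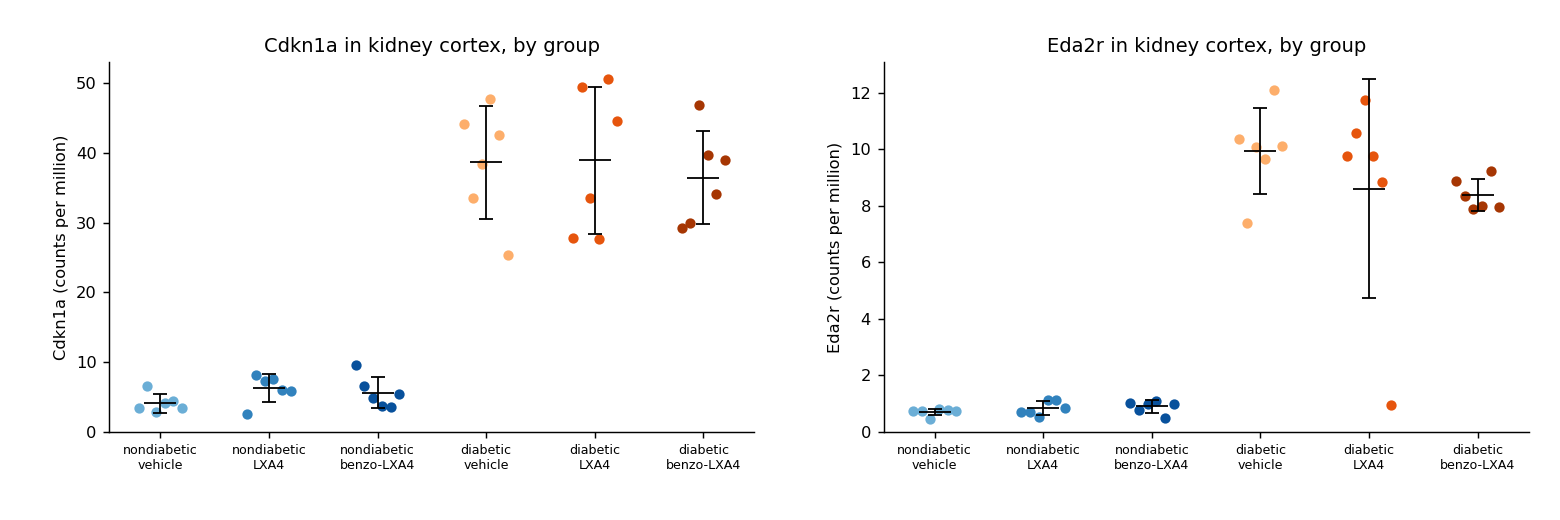
Cdkn1a (left) and Eda2r (right) in CPM in the 6 groups, 1 point per library, with the mean and SD as black bars (n = 6 per group). Mean Cdkn1a was 38.6 CPM in diabetic and 4.09 CPM in nondiabetic vehicle mice, and the low Eda2r point among the diabetic LXA4 libraries, at 0.945 CPM, is replicate 6.

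The other leading rises were Ugt1a10 (log2 4.28, adjusted p = 1.17e-04), Phlda3 (1.88, 0.0121) and Clca3a1 (1.87, 0.00126), and the other leading falls included F5, coagulation factor V (−1.50, 0.0101), Cpne4 (−1.31, 4.97e-04) and the endothelial proteoglycan gene Esm1 (−1.21, 0.00943). Ugt1a10 shares exons with the other Ugt1a genes, and Cyp2d12 and Clca3a1 belong to families of similar sequence, so which member the reads came from is uncertain. In Clca3a1 5 of 6 diabetic libraries lay above the nondiabetic mean, and 6 of 6 lay on the side of the change in the other genes just named. All 13 genes named so far as changed kept an adjusted p under 0.05 when any 1 of the 12 libraries was left out. Of the other leading genes, Ighg2b (immunoglobulin heavy chain, whose segments share sequence) rose by 1.76 (adjusted p = 0.0287, but 0.0625 to 0.0925 without nondiabetic replicate 1, 3, 5 or 6 or diabetic replicate 3 or 4). Car3, carbonic anhydrase 3, fell by 1.98 (0.043, but 0.0535 to 0.108 without nondiabetic replicate 1, 2, 3, 5 or 6 or diabetic replicate 1, 4, 5 or 6). Ces2b, a carboxylesterase, fell by 1.34 (0.0275, but 0.0673 to 0.0882 without nondiabetic replicate 5 or 6 or diabetic replicate 3, 4 or 5). Apoh, apolipoprotein H, fell by 1.31 (0.0178, but 0.0553 to 0.0637 without diabetic replicate 3, 4 or 5). Inmt fell by 1.19 (0.0338, but 0.0594 to 0.106 without nondiabetic replicate 1, 3 or 6 or diabetic replicate 3, 4 or 5). Odc1, ornithine decarboxylase, fell by 1.17 (0.0225, but 0.0563 to 0.0765 without nondiabetic replicate 3 or diabetic replicate 3, 4 or 5), and Fcamr fell by 1.15 (0.0156, but 0.055 to 0.0554 without nondiabetic replicate 1 or diabetic replicate 4). Each of these 7 genes had 6 of 6 diabetic libraries on the side of its change. With only these 2 groups in the fit Ighg2b, F5, Ces2b, Inmt, Odc1 and Fcamr did not pass, and Car3 did not with the filter at a mean of 5 CPM.

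Egr1, an immediate early transcription factor and the gene named in the series title, rose from 3.58 ± 2.09 to 7.57 ± 0.93 CPM in diabetic vehicle mice. Its log2 change was 1.04 (95% interval 0.46 to 1.63, adjusted p = 0.0259), and 6 of 6 diabetic libraries lay above the nondiabetic mean. Without nondiabetic replicate 3 the change was 0.90 (adjusted p = 0.0606), without diabetic replicate 5 it was 1.03 (0.0566), and with only these 2 groups in the fit the adjusted p was 0.109. Of its corepressors, Nab1 differed by 0.06 (adjusted p = 0.774) and Nab2 by −0.08 (0.82). Egr1 (ENSMUSG00000038418) lies on chromosome 18 at 34,859,823 to 34,864,984 on GRCm38.

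Among the fixed lists, genes of the cell cycle and of tissue injury, matrix and inflammation were higher in diabetic mice. These list tests did not hold with an estimated correlation. Of 27 cell cycle genes 10 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 change of 0.62 and, among them, Cdk1 at 1.31, Rrm2 at 0.95 and Mcm5 at 0.82. The list passed with adjusted p = 4.37e-12, and had adjusted p = 0.135 with an estimated correlation. Of 45 extracellular matrix genes 7 rose and 0 fell (17 and 2 adjusted over the list alone; median 0.33, adjusted p = 3.28e-07), among them fibronectin (Fn1, 1.03) and the gelatinase gene Mmp2 (1.30). Of 27 tubular injury genes 4 rose and 0 fell (6 and 0 over the list alone; median 0.35, adjusted p = 9.96e-07), with the stress cytokine Gdf15 at 1.39 and Vcam1 at 0.80. Matrix genes had adjusted p = 0.187 and injury genes adjusted p = 0.177 with an estimated correlation. Of 30 cytokine and NF-kB target genes 3 rose and 0 fell (12 and 0 over the list alone; median 0.27, adjusted p = 3.74e-05, and adjusted p = 0.135 with an estimated correlation), with the chemokine Cxcl10 at 1.49. Markers of T, NK and B cells had a median of 0.57 with 2 of 12 risen (7 over the list alone; adjusted p = 5.46e-04, and 0.187 with an estimated correlation), among them the T cell receptor subunit gene Cd247 at 0.85. Myeloid markers had a median of 0.30 with 1 of 24 risen (1 over the list alone; adjusted p = 6.98e-04, and 0.328 with an estimated correlation), and interferon response genes a median of 0.27 with 2 of 33 risen (2 over the list alone; 1.25e-04, and 0.457 with an estimated correlation). The genes just named kept an adjusted p under 0.05 in every fit that left out 1 library, but other members of the same lists did not. Lgals3 (0.61, adjusted p = 0.0363), Ctss (0.50, 0.0339), Mzb1 (0.89, 0.0469) and Oasl1 (0.92, 0.0377) rose as well and lost their calls without 7, 6, 8 and 9 of the 12 libraries, with adjusted p up to 0.117, 0.102, 0.241 and 0.0866.

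Several other lists also passed upward. Smooth muscle, pericyte and juxtaglomerular markers had a median of 0.33, with 1 of 16 risen (8 over the list alone; adjusted p = 1.34e-04, and 0.135 with an estimated correlation). Genes often described as EGR1 targets had 4 risen and 1 fallen of 25 (4 and 1 over the list alone), a median of 0.09 and a mean of 0.32 (adjusted p = 9.74e-05, and 0.135 with an estimated correlation). Among them Ccnd1, cyclin D1, rose by 1.06 (adjusted p = 1.44e-05). Immediate early genes had 2 of 26 risen (5 over the list alone), a median of 0.15 and an adjusted p = 0.0312 (0.457 with an estimated correlation). Complement and coagulation genes had 4 risen and 2 fallen of 34 (8 and 2 over the list alone; median 0.30, adjusted p = 0.0249, and 0.44 with an estimated correlation), with the plasmin inhibitor gene Serpinf2 at −0.82. Glucocorticoid-responsive genes had 3 risen and 1 fallen of 15 (4 and 1 over the list alone; median 0.34, adjusted p = 0.0333, and 0.475 with an estimated correlation), among them metallothionein Mt1 at 1.12. Aryl hydrocarbon receptor targets had 2 of 7 risen (2 over the list alone; median 0.30, adjusted p = 0.0312, and 0.328 with an estimated correlation), and podocyte markers 0 of 23 in either count (median 0.14, adjusted p = 0.0117, and 0.23 with an estimated correlation). Ccnd1, Serpinf2 and Mt1 kept an adjusted p under 0.05 without any 1 library, but Serpinf2 and Mt1 did not with only these 2 groups in the fit.

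Proximal tubule markers, male-biased and unfolded protein response genes and several metabolic lists were lower in diabetic mice, on tests that did not hold with an estimated correlation. Of 32 proximal tubule markers 0 rose and 5 fell (0 and 11 adjusted over the list alone), with a median log2 change of −0.29 (adjusted p = 3.67e-06, and 0.23 with an estimated correlation). Among them Miox, which breaks down inositol, fell by 0.83 and the fatty acid transporter gene Slc27a2 by 0.55. Of 11 male-biased kidney genes 2 fell (7 over the list alone; median −0.71, adjusted p = 1.61e-06, and 0.187 with an estimated correlation). Fatty acid oxidation genes had 5 of 33 fallen (9 over the list alone; median −0.24, adjusted p = 7.5e-05, and 0.457 with an estimated correlation), and unfolded protein response genes 3 of 28 (10 over the list alone; median −0.35, adjusted p = 7.5e-05, and 0.3 with an estimated correlation). Of 14 gluconeogenesis genes 2 fell (4 over the list alone; median −0.15, adjusted p = 0.0312, and 0.457 with an estimated correlation), among them G6pc, the catalytic subunit of glucose-6-phosphatase, by 1.13. Cholesterol synthesis genes had 3 of 24 fallen (6 over the list alone; median −0.20, adjusted p = 0.00247, and 0.457 with an estimated correlation), and fatty acid synthesis genes 3 of 20 (3 over the list alone; median −0.17, adjusted p = 0.032, and 0.476 with an estimated correlation). Of 49 oxidative phosphorylation genes 0 passed in either count (median −0.16, adjusted p = 5.46e-04, and 0.466 with an estimated correlation). Miox, Slc27a2 and G6pc kept an adjusted p under 0.05 without any 1 library.

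The remaining lists did not pass. Lipoxin and eicosanoid enzymes and receptors had 2 of 19 risen (3 and 1 fallen over the list alone; median 0.13, adjusted p = 0.0794), among them Ltc4s, leukotriene C4 synthase, at 1.32 (adjusted p = 2.29e-04, kept without any 1 library). The renin-angiotensin list had 3 risen and 1 fallen of 22 (3 and 2 over the list alone; median 0.11, adjusted p = 0.21), with the bradykinin receptor gene Bdkrb2 at 1.20 (0.00446, kept without any 1 library). TGF-beta and BMP signalling genes had 2 of 28 risen, among them the BMP antagonist Grem1 at 3.77 (2.63e-04, kept without any 1 library; above the nondiabetic mean in 5 of 6 libraries), but a median of −0.01 and a mean of 0.15 (adjusted p = 0.831). NRF2 targets had 2 risen and 1 fallen of 31 (7 and 5 over the list alone; median 0.06, adjusted p = 0.831). The medians of the mitochondrial mRNA (0.25, adjusted p = 0.116), erythroid (0.36, 0.183), circadian clock (−0.01, 0.296), ribosomal protein (−0.07, 0.329) and liver and pancreas (−0.15, 0.361) lists stayed short of the threshold as well. The same holds for glucose-responsive genes (−0.03, 0.565), collecting duct (−0.09, 0.744) and endothelial markers (−0.03 with a mean of 0.00, 0.827). Median, mean or test differed in sign for adipose markers (median 0.08, mean −0.08, 0.361), female-biased genes (median −0.16, mean 0.28, test downward, 0.827), the loop of Henle and distal convoluted tubule (0.02 and −0.11, 0.859) and glycolysis (−0.01 and 0.04, test downward, 0.956). The adrenal list had fewer than 5 measured members and was not tested.

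In all, 881 of 15,726 genes passed in edgeR, 541 higher and 340 lower in diabetic mice, and 3313 had an unadjusted p under 0.05. The count was 545 without nondiabetic replicate 6, 555, 469 and 441 without diabetic replicates 3, 4 and 5, and 1338 without diabetic replicate 2. Without the 2 libraries rich in structural RNA it was 1399, with 810 genes shared, and DESeq2 called 1329 and voom with quality weights 2221. With only the 2 groups in the fit 342 passed. Of the 77 genes that the naming rule took here and that passed, 34 kept their call whichever library was left out. The genes named with the lists of this comparison come from those 34, except Lgals3, Ctss, Mzb1 and Oasl1.

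The next question, the centre of the series title, is what LXA4 changes in diabetic mice. Egr1 fell from 7.57 ± 0.93 CPM under vehicle to 2.72 ± 0.744 CPM under LXA4 (SD, n = 6 per group), a log2 change of −1.43 (95% interval −2.03 to −0.83, adjusted p = 0.0242), with no overlap between the groups. Cldn1, the tight junction protein claudin 1, fell from 20.3 ± 1.98 to 11.5 ± 3.96 CPM (−0.78, interval −1.10 to −0.47, 0.0197), and Ddc, which makes dopamine from L-DOPA, from 81.4 ± 16.4 to 53.7 ± 7.49 CPM (−0.60, 0.0472). The clock gene Per2 rose from 43 ± 17 to 93.1 ± 35.8 CPM (1.12, interval 0.61 to 1.64, 0.0405). Lamb3, a laminin chain of basement membranes, rose from 9.05 ± 1.5 to 17.3 ± 4.03 CPM (0.94, interval 0.56 to 1.31, 0.0197). The other leading rises were Lonrf3 (log2 0.95), Mpp4 (0.89), Cys1 (0.69), Kmt2d (0.63), Zbtb40 (0.58), Ngef (0.57) and Catsper2 (0.57), with adjusted p from 0.0176 to 0.0486, and the other falls Pcdh18 (−0.73) and Wbp5 (−0.56), both at 0.0472. In Per2 and Mpp4 5 of 6 LXA4 libraries lay on the side of the change from the vehicle mean, and in the other genes just named 6 of 6 did. Kmt2d was 0.63 with all libraries and 0.32 without the 2 rich in structural RNA (adjusted p = 0.00858), and Cys1, Pcdh18 and Ddc did not pass without them (0.0663, 0.0546 and 0.0559). Nab1 (−0.14), Nab2 (0.10) and Apoe (0.32, adjusted p = 0.345) did not pass. These calls depended on single libraries of both groups. In edgeR 56 genes passed, 49 higher and 7 lower, and 2468 had an unadjusted p under 0.05. The count was 0 without diabetic vehicle replicate 2, 1 without replicate 3, 19 without replicate 5 and 36 without replicate 6, and 16, 30 and 88 without diabetic LXA4 replicates 2, 4 and 5. Egr1 had an adjusted p of 0.0531, 0.0722 and 0.0505 without diabetic vehicle replicates 2, 3 and 5, with log2 changes from −1.53 to −1.37 over all fits that left out 1 library. Each of the genes named here lost its call without diabetic vehicle replicate 2, and all but Zbtb40 without replicate 3. Catsper2 kept it without any other library, Lamb3, Ngef and Egr1 lost it also without replicate 5, and Cldn1 also without diabetic LXA4 replicate 2. The other 8 lost it without 6 to 9 of the 12 libraries, with adjusted p up to 0.147. With only the 2 groups in the fit 1 gene passed, Egr1 (0.019), while DESeq2 called 231 genes, voom with quality weights 172, and edgeR 93 without the 2 libraries rich in structural RNA, 44 of them shared.

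**Figure D3:**
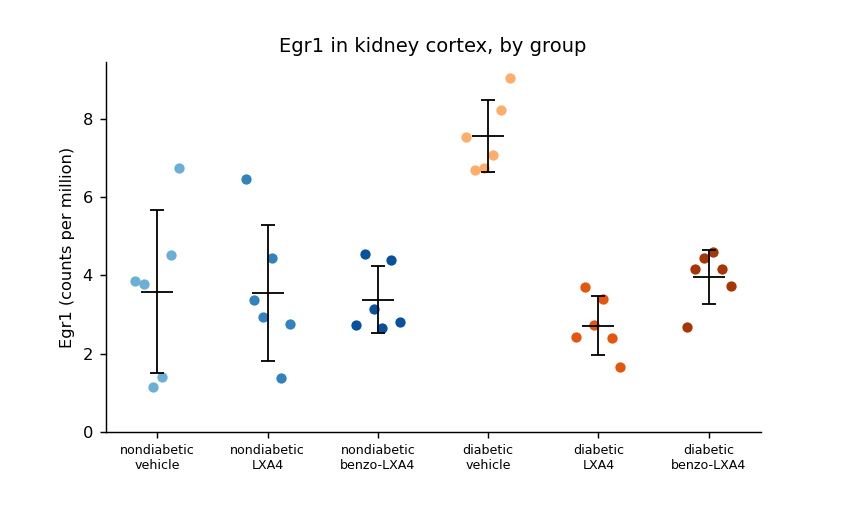
Egr1 in CPM in the 6 groups, 1 point per library, with the mean and SD as black bars (n = 6 per group). The diabetic vehicle libraries lie between 6.71 and 9.06 CPM, and the diabetic LXA4 libraries between 1.65 and 3.71 CPM.

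By list, ribosomal protein genes were lower and clock genes higher in LXA4-treated diabetic mice, on tests that did not hold with an estimated correlation. The 47 ribosomal protein genes had a median log2 change of −0.29 (adjusted p = 9.67e-12), NRF2 targets −0.18 (1.61e-04), oxidative phosphorylation genes −0.13 (1.61e-04), cholesterol synthesis genes −0.21 (1.86e-04), erythroid genes −0.39 (9.57e-04) and cell cycle genes −0.24 (0.0014). Clock genes had a median of 0.38 (0.00128) with 2 of 17 risen (4 over the list alone), glucocorticoid-responsive genes 0.23 (0.027) and endothelial markers 0.15 (0.0449). Each of these 9 lists had adjusted p = 0.576 with an estimated correlation. Of 100 splits of the same libraries, the real one included, 29 called at least as many lists. Genes often described as EGR1 targets had a median of −0.02, a mean of 0.04 and a test pointing downward (adjusted p = 0.423), with 1 of 25 fallen.

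Benzo-LXA4 in diabetic mice gave no gene past the threshold in edgeR. Egr1 stood at 3.96 ± 0.694 CPM against 7.57 ± 0.93 CPM under vehicle (SD, n = 6 per group), with all 6 benzo-LXA4 libraries below all 6 vehicle libraries. Its log2 change was −0.93 with a 95% interval of −1.51 to −0.35, but its adjusted p was 0.414 over all genes. It passed with voom with quality weights (adjusted p = 0.0401) and with only the 2 groups in the fit (0.0437), and did not without the 2 libraries rich in structural RNA (0.0932). The genes with the smallest p were Zmiz1 (log2 0.34, adjusted p = 0.179), Rptor (0.24, 0.181), Atp2b2 (0.57, 0.187), Fam188b (0.25, 0.187) and Dscaml1 (1.01, 0.187). Nab1 (−0.06), Nab2 (0.05) and Apoe (0.09) did not pass either. In edgeR 0 genes passed and 891 had an unadjusted p under 0.05, and DESeq2 called 52 and voom with quality weights 105. EdgeR called 3 with only the 2 groups in the fit, and 48 without the 2 libraries rich in structural RNA, among them Zmiz1 (0.0108). Neither of those libraries is in the groups compared here. They bear on this count only through the filter, scaling and spread that all groups share. The edgeR count stayed 0 whichever 1 library of these 2 groups was left out.

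Of the lists, erythroid genes had a median log2 change of −0.68 under benzo-LXA4 (adjusted p = 3.04e-11, and 0.0835 with an estimated correlation; 5 of 9 fallen over the list alone, 0 over all genes). Ribosomal protein genes had a median of −0.15 (5.48e-07), extracellular matrix genes −0.10 (0.00173), immediate early genes −0.17 (0.014) and genes often described as EGR1 targets −0.09 (0.0295), each with adjusted p = 0.542 with an estimated correlation. In all 15 lists passed with the preset correlation and 0 with an estimated one.

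LXA4 and benzo-LXA4, which differ in the fused benzene ring, were given at different doses, 5 and 1.7 µg/kg, and no gene differed between them past the threshold in diabetic mice. Both shared the same vehicle libraries, so their changes are not independent of each other. Egr1 changed by −1.43 with LXA4 and was at −0.93 with benzo-LXA4, a difference of 0.50 (95% interval −0.10 to 1.10, adjusted p = 0.72). Per2 was at 1.12 and 0.43 (difference −0.70, interval −1.20 to −0.19), Lonrf3 at 0.95 and 0.17 (−0.78, −1.22 to −0.34) and Cldn1 at −0.78 and −0.27 (0.52, 0.20 to 0.83). These intervals leave out 0, but no adjusted p was under 0.717. Apart from Egr1, the genes set side by side here were picked for passing under LXA4 in these libraries. A smaller change with benzo-LXA4 would therefore be likely even if both compounds acted alike. Egr1 is named in the series title, so its choice may rest on these same libraries, and the same may hold for it. Lamb3 was at 0.94 and 0.62 (−0.31, −0.68 to 0.06), Ngef at 0.57 and 0.47 (−0.10, −0.33 to 0.13), Ddc at −0.60 and −0.43 (0.17, −0.12 to 0.45) and Wbp5 at −0.56 and −0.57 (interval of the difference −0.27 to 0.26). The smallest p-values belonged to Igha (log2 1.97, benzo-LXA4 higher), Jchain (1.68), Prss23os (1.22), Tmem57 (−0.28) and Baz1b (−0.34), all with adjusted p = 0.717. In edgeR 0 genes passed and 1089 had an unadjusted p under 0.05, and DESeq2 and voom with quality weights called 0 as well. Cell cycle genes were higher with benzo-LXA4 than with LXA4 by a median of 0.37 (adjusted p = 1.2e-06, and 0.573 with an estimated correlation), and clock genes lower by a median of −0.30 (0.00975, and 0.587 with an estimated correlation; 0 over all genes and 4 over the list alone fallen).

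**Figure D4:**
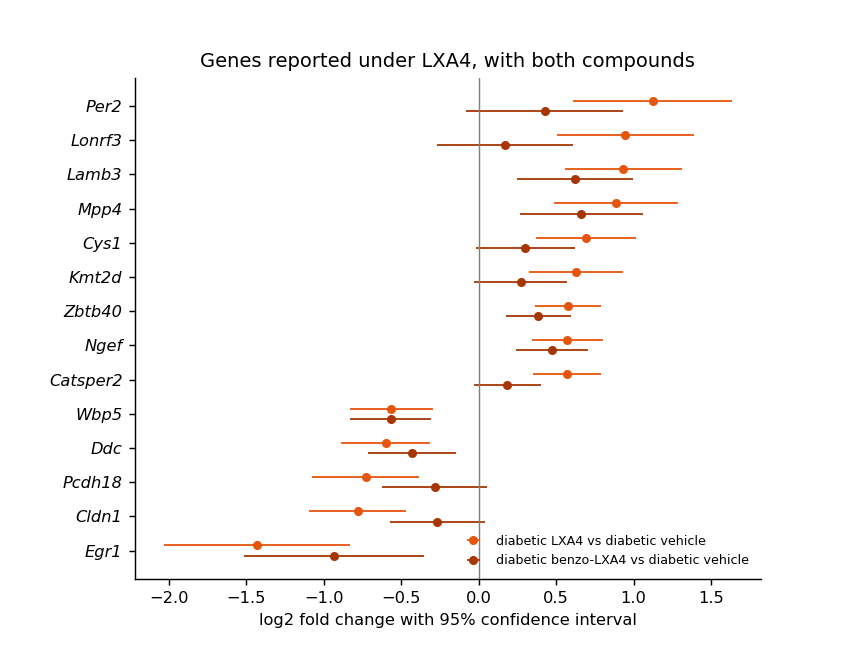
Log2 fold changes against diabetic vehicle mice (horizontal axis) of the genes reported under LXA4, for LXA4 and benzo-LXA4, with 95% confidence intervals as bars. Egr1 lies at −1.43 with LXA4 and −0.93 with benzo-LXA4, and Per2 at 1.12 and 0.43. All genes but Egr1 were picked for their change under LXA4. Egr1 is named in the series title, so its choice may rest on the same libraries.

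In nondiabetic mice neither compound changed a gene past the threshold in edgeR. Egr1 stood at 3.56 ± 1.74 CPM with LXA4 and 3.38 ± 0.862 CPM with benzo-LXA4, against 3.58 ± 2.09 CPM with vehicle (log2 −0.04, interval −0.63 to 0.55, and −0.12, interval −0.72 to 0.47). With LXA4 the smallest p-values belonged to Gm15492 (−0.65), Kdm4b (−0.32), Gm26704 (−1.25), Syne3 (−0.57) and 0610043K17Rik (0.43), with adjusted p from 0.314 to 0.573. Here 967 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 3 genes and voom with quality weights 3. With benzo-LXA4 they belonged to Kcnk3 (3.75), Thrsp (3.92), Fasn (2.23), Mrap (3.38) and Adam12 (0.84), all with adjusted p = 0.617. Nondiabetic benzo-LXA4 replicate 1 held 87.7% of the Kcnk3, 89.9% of the Thrsp, 77.4% of the Fasn and 89.7% of the Mrap of its group, and adipose markers had a median of 4.36 in this comparison (adjusted p = 0.00191, and 0.597 with an estimated correlation). Here 452 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 called 2 genes and voom with quality weights 0. Between the compounds, where the doses differ too, 0 genes passed in edgeR and 1319 had an unadjusted p under 0.05 (DESeq2 2, voom with quality weights 30), led by Grm7 (0.78, adjusted p = 0.229), Dnaic1 (1.07, 0.338), Zfp422 (−0.32), Gja5 (0.68) and Gng7 (0.79). By list, with LXA4 unfolded protein response genes had a median of 0.20 (adjusted p = 5.51e-06, and 0.719 with an estimated correlation). With benzo-LXA4 extracellular matrix genes had a median of 0.15 (2.71e-06, and 0.332 with an estimated correlation).

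Whether LXA4 acts differently in diabetic and nondiabetic mice was tested with the interaction. Ddc had an interaction of −1.05 on the log2 scale (95% interval −1.45 to −0.64, adjusted p = 0.0212), with 53.7 CPM under LXA4 against 81.4 under vehicle in diabetic mice and 79.5 against 58.4 in nondiabetic mice. Lamb3 (1.45, interval 0.91 to 1.98, 0.0191), Per2 (1.54, 0.0485) and Cldn1 (−1.07, 0.0323) also passed. Egr1 had an interaction of −1.39 (interval −2.23 to −0.55) that missed the threshold in edgeR (adjusted p = 0.121) and passed in DESeq2 (0.0424). Aldh1a3, a retinaldehyde dehydrogenase gene, had the largest interaction, 8.17 (0.0342), but diabetic LXA4 replicate 5 held 95.8% of its group's level and nondiabetic vehicle replicate 2 held 92.3%. Without the first of these it was 3.90 (adjusted p = 0.176) and without the second 4.70 (0.211). Among the groups compared, these libraries also had the highest scores for urothelium and inner medulla markers, and Lamb3 was highest of its group in both, at 24.27 and 17.97 CPM. With both scores as covariates, a test chosen after the data were examined, the interaction was 2.58 (0.459) for Aldh1a3. It was 1.32 (0.0458) for Lamb3, −0.998 (0.0458) for Ddc, 1.63 (0.0697) for Per2 and −1.07 (0.0553) for Cldn1, and 13 of the 39 calls held. Clock phase at harvest was not tested as a source of these interactions. For benzo-LXA4 0 genes passed in edgeR, 673 had an unadjusted p under 0.05, and DESeq2 and voom with quality weights called 0. The smallest p-values belonged to the haemoglobin genes Hba-a2 (−1.47) and Hbb-bs (−1.65), whose family members share sequence, and to Myl9 (−0.69), Srpx (−1.24) and Fam169b (0.57), all with adjusted p = 0.888. The erythroid list had a median interaction of −1.19 with benzo-LXA4 (adjusted p = 5.03e-16), the 1 fixed list that also passed with an estimated correlation (0.0144), with 7 of 9 genes lower over the list alone and 0 over all genes. For LXA4 39 genes had an interaction past the threshold in edgeR, 33 positive and 6 negative, and 2592 an unadjusted p under 0.05. Every named gene among them lost its call without diabetic vehicle replicate 3, where 0 genes passed and Lamb3 and Ddc had an adjusted p of 0.0512. These kept it without any other library, while Cldn1 lost it without 7 of the 24 libraries, Aldh1a3 without 14 and Per2 without 17. The count was 9, 24, 5, 106 and 79 without nondiabetic vehicle replicates 2 to 6, and 13, 7, 10, 6 and 13 without nondiabetic LXA4 replicates 1, 2, 3, 4 and 6. It was 7, 71 and 21 without diabetic vehicle replicates 2, 4 and 6, and 67, 63, 69, 8, 76 and 59 without diabetic LXA4 replicates 1 to 6. With only the 4 groups in the fit 0 genes passed, while DESeq2 called 266, voom with quality weights 211, and edgeR 129 without the 2 libraries rich in structural RNA, 38 of them shared.

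The direction of all 881 diabetes genes under each compound was compared with simulated groups, to gauge what shared vehicle libraries alone would give. Under LXA4 77.4% of them moved opposite to diabetes, against 59.8% on average (56.5 to 63.2%) in 20 simulated groups without a treatment effect, where 630 to 680 genes were called for diabetes. Under benzo-LXA4 the share was 75.4%, against 59.4% (56.1 to 62.6%). The simulations took the estimated diabetes changes as true and drew each gene independently. Their shares may therefore be too low, and their ranges leave out variation shared between genes. When the 6 diabetic vehicle libraries were split so that each comparison had its own 3, the mean share over the 20 splits was 61.7% for LXA4 (30.2 to 76.4%, over 50% in 17) and 57.4% for benzo-LXA4 (23.7 to 78.3%, over 50% in 16). The splits called 81 to 2155 diabetes genes, and the share was lower where more were called. For LXA4 it was 30.2% over 2155 genes and 76.4% over 106, so these shares are not over the same 881 genes. Cdkn1a and Eda2r, the leading diabetes genes, stood at 38.9 ± 10.6 and 8.60 ± 3.87 CPM with LXA4, against 38.6 ± 8.11 and 9.95 ± 1.52 CPM with vehicle.

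Treated diabetic mice were last compared with nondiabetic vehicle mice, to see which diabetes differences were still present under each compound. Cdkn1a was higher by 3.23 on the log2 scale with LXA4 (adjusted p = 9.15e-11) and by 3.14 with benzo-LXA4 (1.9e-10), Eda2r by 3.63 (1.97e-11) and 3.53 (3.77e-11), Trp53cor1 by 3.43 (4.38e-12) and 3.52 (1.2e-12), and Dscaml1 by 3.58 (1.78e-11) and 3.97 (1.2e-12). F5 was lower in both comparisons (−2.03, adjusted p = 0.00103, and −1.72, 0.00361), as were Cpne4 (−1.68 and −1.57) and Cyp2d12 (−1.72 and −1.58). Egr1 did not differ past the threshold from its level in nondiabetic vehicle mice with LXA4 (−0.39, adjusted p = 0.432) or with benzo-LXA4 (0.11, 0.873), and neither did Apoe (0.33 and 0.10). Nab1 and Nab2 did not pass in any comparison. Each change named here as passing kept an adjusted p under 0.05 without any 1 library, and 6 of 6 treated libraries lay on its side of the nondiabetic mean. The nondiabetic vehicle libraries serve both comparisons and the diabetes comparison.

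With LXA4 the other leading rises were Ugt1a10 (2.97), Phlda3 (2.78), Kcnip4 (2.32), Adamtsl3 (2.12), Sh3rf3 (2.06) and Kynu (1.81), and the other leading falls Apoh (−1.83), Slc17a4 (−1.51) and Dio1, which converts thyroxine to its active form (−1.20), with adjusted p from 7.97e-10 to 0.006. With benzo-LXA4 the cell cycle genes Mki67 (1.70), Cdk1 (1.44), Birc5 (1.60) and Rrm2 (1.16) rose, with adjusted p from 4.08e-04 to 0.0011. Plcd4 rose by 1.68 (adjusted p = 2.25e-10), and Car3 fell by 2.92 (0.00404). Ugt1a10 and Kynu lay above the nondiabetic mean in 5 of 6 LXA4 libraries, and the other genes just named in 6 of 6 on the side of their change. All kept an adjusted p under 0.05 without any 1 library. Other leading falls did not: Igfbp1 (−1.53, adjusted p = 0.0125), Ces2b (−1.27, 0.029) and Etv1 (−1.15, 0.0199) with LXA4 lost their calls without 1, 4 and 2 of the 12 libraries. With benzo-LXA4 Col8a1 (−1.24, 0.0265), Pde6a (−1.16, 0.0247) and Smim22 (−1.15, 0.0249) did so without 6, 6 and 3. Of the genes that the naming rule took and that passed, 54 of 99 with LXA4 and 43 of 74 with benzo-LXA4 kept their call whichever library was left out. With only the 2 groups in the fit Ugt1a10, Kynu, Dio1 and Cyp2d12 did not pass in the LXA4 comparison.

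With LXA4 cholesterol synthesis genes had 0 risen and 9 fallen of 24 (14 fallen over the list alone; median −0.45, adjusted p = 2.56e-09, and 0.272 with an estimated correlation), led by Cyp51 (−0.77) and Ebp (−0.63), which kept their calls without any 1 library but not with only the 2 groups in the fit. Oxidative phosphorylation genes had 9 of 49 fallen (22 over the list alone; median −0.30, 2.13e-10, and 0.293 with an estimated correlation), ribosomal protein genes 7 of 47 (13 over the list alone; median −0.28, 2.13e-10, and 0.294 with an estimated correlation) and interferon response genes 8 of 33 risen (13 over the list alone; median 0.49, 9.68e-06, and 0.345 with an estimated correlation). With benzo-LXA4 cell cycle genes had 14 of 27 risen (20 over the list alone; median 0.73, 1.68e-13, and 0.255 with an estimated correlation) and unfolded protein response genes 6 of 28 fallen (15 over the list alone; median −0.38, 2.13e-05, and 0.302 with an estimated correlation). Fatty acid oxidation genes had 6 of 33 fallen with benzo-LXA4 (9 over the list alone; median −0.34, 2.93e-06, and 0.374 with an estimated correlation).

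With LXA4 1370 genes differed from nondiabetic vehicle mice in edgeR, 660 higher and 710 lower, but 772 and 708 without nondiabetic vehicle replicates 5 and 6, 2431 without diabetic LXA4 replicate 6, and 120 with only the 2 groups in the fit. With benzo-LXA4 961 differed, 535 higher and 426 lower, but 628 and 543 without nondiabetic vehicle replicates 3 and 6, 522 without diabetic benzo-LXA4 replicate 5 and 522 without replicate 6. Without the 2 libraries rich in structural RNA the counts were 1770 and 1799.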

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

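The tests of the p53 target genes, of the fast immediate early genes, of tissue beyond the cortex and of the 2 libraries rich in structural RNA were chosen after the results were seen. So was the share of the change left, used to read the length and clock tests. The splits of all 36 libraries and the length and clock tests themselves were chosen before. The splits without the 2 libraries rich in structural RNA, and the clock test, rest on a choice of libraries made after seeing the data. List calls in splits were read after the results were seen in all but the first 3 comparisons, diabetes and each compound in diabetic mice.

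A sample standing apart from the other 5 of its group was looked for in 84 groups of values with Dixon's test, which chance meets in about 1 in 20 groups; 12 met it. In nondiabetic vehicle replicate 3, ribosomal and small structural RNA genes took 17.6% of the counts (next 3.32%), the median correlation with the other libraries was 0.957, and Eda2r stood at 0.458 CPM. In diabetic LXA4 replicate 6 these RNA genes took 56.8% (next 5.93%), of which 38.0% of all counts were from Gm26917, the median correlation was 0.883, and Nab1 stood at 20.5 CPM, Nab2 at 15.8 CPM and Eda2r at 0.945 CPM (next 8.85 CPM). Nondiabetic LXA4 replicate 3 had 6.80% structural RNA, replicate 1 had Nab1 at 41.8 CPM and replicate 4 had Cldn1 at 14.9 CPM. Nondiabetic benzo-LXA4 replicate 1 had a median correlation of 0.968.

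The effect of LXA4 differed between diabetic and nondiabetic mice, by the interaction test, in 39 genes. The interactions named were 8.17 for Aldh1a3, 1.54 for Per2, 1.45 for Lamb3, 0.91 for Syne3, 0.78 for Hdac7, 0.77 for Cbfa2t3, 0.74 for Ngef, 0.69 for Fam102a, 0.56 for Kdm4b and 1.82 for 1600010M07Rik on the log2 scale. They were −1.22 for Stra6l, −1.07 for Cldn1, −1.05 for Ddc, −0.72 for Tuba4a, −0.62 for Med28 and −0.58 for Sumo3. All of these calls ended without diabetic vehicle replicate 3, where 0 genes passed. For Aldh1a3 the value was 3.90 (adjusted p = 0.176) without diabetic LXA4 replicate 5 and 4.70 (0.211) without nondiabetic vehicle replicate 2, libraries that had the highest scores for urothelium and inner medulla markers among the groups compared. With both scores as covariates the interaction was 2.58 (0.459) for Aldh1a3, and 1.32 (0.0458) for Lamb3, which was also highest of its group in these libraries. Clock phase at harvest was not tested as a source of the interactions. On the first component of the clock genes, nondiabetic LXA4 libraries lay at 0.0852 to 1.94. Diabetic LXA4 replicates 1 to 4 lay at −2.06 to −0.929 and replicate 5 at 1.68, and vehicle libraries of both states between −0.944 and 1.43.

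Other splits of the same libraries, 100 per comparison with the real one included, show how often random groupings give as many calls. Splits that mix the groups unevenly keep part of any real difference, so they do not show chance alone. These tests were not adjusted for their number. For diabetes 3 splits gave at least the real 881 genes, the highest other 2720. For LXA4-treated diabetic against nondiabetic vehicle mice 4 gave at least 1370, the highest other 2634, and for the same with benzo-LXA4 2 gave at least 961, the highest other 1141. Few splits reached these counts, so chance is unlikely but not excluded. The split with 2720 genes, several times the real count, points to a structure of the samples other than the groups. Which structure it is was not settled. The first part of this split held 2 diabetic libraries, so it may also keep some of the diabetes difference. Of 4 lists scored, the parts of this split differed most in mean log2 inner medulla score, by 2.21, a difference that 0 other splits exceeded. For urothelium, brown fat and the other p53 targets 9, 11 and 35 splits did. In the split with 2634 genes 4 splits exceeded the inner medulla difference of 1.79, and 15, 41 and 34 those of the other lists. Chance is unlikely too for LXA4 in diabetic mice, where 1 split, the real one, gave 56 genes and the highest other 42. It is also unlikely for the LXA4 interaction, where 1 gave 39 and the highest other 1. Without the 2 libraries rich in structural RNA 4 gave at least 93 genes for LXA4 (highest other 1068), 1 gave 48 for benzo-LXA4 (highest other 6) and 2 gave at least 129 for the interaction (highest other 1157). Chance is unlikely for these too, but splits with 1068 and 1157 genes again point to a structure of the samples. Where the real count was 0, all 100 splits gave at least as many, which was fixed in advance and tests nothing. The highest other counts there were 1 for benzo-LXA4 in diabetic mice and 0 for the benzo-LXA4 interaction. In nondiabetic mice they were 1 for LXA4 and 34 for benzo-LXA4. Between the compounds they were 1 in diabetic and 38 in nondiabetic mice. For list calls, chance is unlikely for diabetes, where 1 split, the real one, reached 22 (highest other 21). In treated diabetic against nondiabetic vehicle mice 2 reached 22 with LXA4 (highest other 23) and 4 reached 21 with benzo-LXA4 (highest other 24). Chance is unlikely there too. Between the compounds in diabetic mice 4 reached 15 (highest other 18), but camera with an estimated correlation and fry called 0 lists there. Chance is therefore not excluded for that comparison. Splits gave as many lists more often in diabetic mice for LXA4, where 29 reached 9 (highest other 15), and for benzo-LXA4, where 12 reached 15 (highest other 21). The same held in nondiabetic mice for LXA4 (71 reached 6), for benzo-LXA4 (23 reached 15) and between the compounds (88 reached 8). It also held for the interactions of LXA4 (27 reached 11) and benzo-LXA4 (41 reached 14).

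The first pattern is that targets of p53, the DNA damage-responsive transcription factor, were higher in diabetic mice: 12 targets seen among the leading genes had a median log2 change of 1.08, and 28 other targets one of 0.31 (adjusted p = 5.8e-04 with an estimated correlation). The tables argue against a few libraries as the source, since 18 of 18 diabetic libraries had a mean over the other targets above the highest nondiabetic library (4.134 at the lowest against 4.128). Cells of another type stay open: the highest median among cell type marker lists was 0.568, for T, NK and B cells, below 1.08 but above the smaller change of the other targets. An effect of streptozotocin itself, which damages DNA, cannot be told apart from diabetes, since 0 nondiabetic groups received it. A response to diabetes is the biological candidate explanation and was not tested apart from streptozotocin.

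The second pattern is the 56 genes that passed under LXA4 in diabetic mice. The tables argue against the 2 libraries rich in structural RNA as the whole cause, since 44 of the 56 passed without them. They also argue against urothelium and inner medulla, 2 kinds of tissue beyond the cortex, whose scores 2070 genes followed. With both scores as covariates 0.986 of the mean change was left (95% interval over libraries 0.937 to 1.04), and 36 of the 56 kept their call. The other calls ended as the median size went from 0.492 to 0.468, with an SE of 0.106 before and 0.105 after. Brown fat was not tested in this way. Transcript length and GC content stay open: the called genes have a median longest transcript of 5070.5 bases against 3228 for all genes. With each library's trend removed 50 kept their direction at an unadjusted p under 0.05 but 5 kept their call, because the median size of the log2 change fell from 0.492 to 0.327 while its SE was 0.106 before and 0.103 after. Of the mean change 0.808 was left (interval 0.629 to 0.986). Without the 2 libraries rich in structural RNA 54 of the 56 kept their direction at an unadjusted p under 0.05 with the trend removed. There 14 kept their call, against 44 with the trend left in, at median sizes of 0.317 and 0.386 and SEs of 0.0894 and 0.0873, so the drop in size was smaller in those libraries. Clock phase at harvest stays open too. With 2 clock components as covariates 46 of 54 genes kept their direction at an unadjusted p under 0.05, and the median size was 0.377 against 0.379 without covariates in the same 34 libraries. The calls, 42 without covariates and 1 with them, ended with a rise of the SE from 0.0854 to 0.122, which does not show that the clock explains the changes. Of the mean change 0.845 was left, but with an SE of 0.149 and an interval reaching down to 0.552. The bound written before, 3 in 4 genes at an unadjusted p under 0.05, was met in both tests. It is not read as exclusion, since genes picked for a small p carry noise that no correction removes, and neither share left lay above 3 in 4 by more than its spread.

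The third pattern is Egr1, higher in diabetic vehicle mice than in treated diabetic mice. Its change passed under LXA4 but not under benzo-LXA4 (adjusted p = 0.414), and the checks here are for LXA4 only. The LXA4 call ended without diabetic vehicle replicate 2, 3 or 5 (adjusted p = 0.0531, 0.0722 and 0.0505). The tables argue against the 2 libraries rich in structural RNA, since the change under LXA4 was −1.38 (adjusted p = 0.0185) without them, against −1.43 with them. A handling response shared by fast immediate early genes stays open: the median of 9 such genes was 0.109 (interval −0.59 to 0.419), but they went both ways, with Fos at −1.29 and Nr4a1 at −0.88, neither past the threshold, and Dusp1 at 0.73. In the diabetes comparison Fos was at 1.26 and Nr4a1 at 1.10, the same pattern as Egr1, though neither passed. Dusp1 was at −0.43 there, and the median of the 9 genes was 0.08. Clock phase at harvest stays open, since with 2 clock components the change was −1.06 (SE 0.378, unadjusted p = 0.0087, adjusted p = 0.215), against −1.38 in the same 34 libraries without them. The share left, 0.77, met the bound of 3 in 4 written before, but not by more than its spread (interval 0.439 to 1.10). An effect of the lipoxins on Egr1 is the biological candidate explanation, and these tests may not separate it from the conditions of harvest, which the labels do not give.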

How the results depend on the processing

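All alternatives below were chosen before the data were examined, except leaving out the 2 libraries rich in structural RNA, nondiabetic vehicle replicate 3 and diabetic LXA4 replicate 6, which was chosen after seeing the data. RLE size factors and no filter left every count of genes within 1.5 times the value reported. The share of diabetes genes moved the opposite way was computed under some alternatives only. These were RLE size factors, DESeq2, the filter at a mean of 5 CPM, the replicate block and leaving out the 2 libraries. In each of them most diabetes genes still moved the opposite way. No named gene that passed changed its direction under any alternative that tested it. None did with any 1 library of the groups compared left out. The filter at a mean of 5 CPM removed Egr1, so Egr1 was not tested under that alternative. Of the 77 genes named in the diabetes comparison that passed, 34 kept their call whichever library was left out, against 0 of 15 in the LXA4 comparison in diabetic mice and 0 of 18 in the LXA4 interaction, 54 of 99 with LXA4 and 43 of 74 with benzo-LXA4 against nondiabetic vehicle mice.

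The number of genes called depended on the model. DESeq2 called 1329 genes for diabetes, 231 for LXA4 and 52 for benzo-LXA4 in diabetic mice, 3 for LXA4 and 2 for benzo-LXA4 in nondiabetic mice, 2 between the compounds in nondiabetic mice, 266 for the LXA4 interaction and 1491 for benzo-LXA4-treated diabetic against nondiabetic vehicle mice. Voom with sample quality weights called, in the same order, 2221, 172 and 105, then 3 for LXA4 in nondiabetic mice, 30 between the compounds there, 211 for the LXA4 interaction, and 3757 with LXA4 and 3579 with benzo-LXA4 against nondiabetic vehicle mice. The cause was not tested for either model. With only the compared groups in the fit, which leaves fewer libraries to estimate the spread, the counts were 342 for diabetes, 1 for LXA4, 3 for benzo-LXA4, 0 for the LXA4 interaction and 120 for LXA4-treated diabetic against nondiabetic vehicle mice. A filter at a mean of 5 CPM, which tests fewer genes, gave 442 genes for diabetes, 80 for the LXA4 interaction and 577 for benzo-LXA4-treated diabetic against nondiabetic vehicle mice. Without the 2 libraries rich in structural RNA the counts were 1399 for diabetes, 93 for LXA4, 48 for benzo-LXA4 and 129 for the LXA4 interaction. For benzo-LXA4-treated diabetic against nondiabetic vehicle mice the count was 1799, and 15 lists were called for LXA4. Neither library is in the groups compared for benzo-LXA4 in diabetic mice. The rise to 48 there came through the filter, scaling and spread that all groups share. Otherwise the cause was not tested.

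Replicate numbers recur in every group, so the replicate number as a block was tried. It gave 28 genes for LXA4 in diabetic mice and 9 for the LXA4 interaction, and left the other counts within 1.5 times. Correlations of deviations from the group mean between libraries of the same number in different groups had a median of −0.00349, against −0.00307 for other libraries, and 4 of 36 libraries correlated best with one of their own number, so the numbers do not pair the samples.

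With 1 library left out the count ran from 441 (diabetic vehicle replicate 5) to 1338 (replicate 2) for diabetes, and from 0 (diabetic vehicle replicate 2) to 88 (diabetic LXA4 replicate 5) for LXA4 in diabetic mice. It ran from 0 (diabetic vehicle replicate 3) to 106 (nondiabetic vehicle replicate 5) for the LXA4 interaction, from 708 to 2431 for LXA4-treated diabetic against nondiabetic vehicle mice and from 522 to 1406 for the same with benzo-LXA4. The cause was not tested. In the other 6 comparisons 0 genes passed in edgeR whichever library of the groups compared was left out.

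Calls of the fixed lists depended on the test. With an estimated correlation camera called 0 of them in every comparison but the benzo-LXA4 interaction, where it called 1. Fry called 14 lists for diabetes, 13 for benzo-LXA4-treated diabetic against nondiabetic vehicle mice, 1 for the benzo-LXA4 interaction and 0 in the treatment comparisons within a state, in the comparison of the compounds in either state and in the LXA4 interaction. With the filter at 5 CPM 8 lists were called for benzo-LXA4 in nondiabetic mice and 8 between the compounds in diabetic mice. The share of diabetes genes moved the opposite way was 61.7% for LXA4 and 57.4% for benzo-LXA4 on average over the 20 splits of the diabetic vehicle libraries; the split removes the sharing of these libraries, leaves 3 in each comparison and changes the number of diabetes genes called (81 to 2155).

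Only genes that did not pass changed sign. Against nondiabetic vehicle mice, Apoe in diabetic vehicle mice was −0.027 with voom and ran from −0.079 to 0.083 with 1 library left out, and Nab2 was 0.072 without the 2 libraries rich in structural RNA and ran from −0.16 to 0.066. In LXA4-treated diabetic mice Nab1 was 0.0066 without the 2 libraries and 0.024 with voom and ran from −0.12 to 0.043, and Nab2 was −0.0038 with voom and ran from −0.12 to 0.15. In benzo-LXA4-treated diabetic mice Egr1 was −0.030 without the 2 libraries and −0.084 with voom and ran from −0.049 to 0.39, Nab1 was −0.017 without the 2 libraries and ran from −0.028 to 0.053, and Nab2 was 0.011 with the filter at 5 CPM, 0.13 without the 2 libraries and 0.077 with voom and ran from −0.10 to 0.12. In nondiabetic mice Egr1 ran from −0.29 to 0.24 and Nab2 from −0.047 to 0.19 under LXA4, and Egr1 ran from −0.29 to 0.15 under benzo-LXA4. For LXA4 against vehicle in diabetic mice Nab2 was −0.056 without the 2 libraries and ran from −0.054 to 0.15. Between the compounds in diabetic mice Nab1 was −0.024 without the 2 libraries and −0.018 with voom and ran from −0.027 to 0.13, and Nab2 was 0.11 and 0.081 and ran from −0.10 to 0.11. Between them in nondiabetic mice Egr1 was 0.052 with voom and ran from −0.25 to 0.17, and Nab1 ran from −0.031 to 0.046. In the LXA4 interaction Nab2 was −0.25 without the 2 libraries and −0.14 with voom and ran from −0.10 to 0.15.

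Depth limits genes with few counts. Apoe, Egr1 and Eda2r lay under 10 CPM in every group, and in the shallowest library, with 8,896,193 counts of which 56.8% were structural RNA, each such gene rests on few counts.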

Other observations

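All tests of the lists below were chosen after the data were examined. Urothelium and inner medulla markers mark tissue beyond the cortex, and their levels differed between libraries of the same group. Urothelium markers had a median log2 change of −2.14 with LXA4 in nondiabetic mice (adjusted p = 7.08e-06, and 0.289 with an estimated correlation) and of 1.49 with LXA4 in diabetic mice (0.0242, and 0.747 with an estimated correlation), and an interaction of 3.57 (2.87e-05, and 0.536 with an estimated correlation; 11 genes over the list alone). Between the compounds in nondiabetic mice they differed by 2.56 (4.88e-07, and 0.39 with an estimated correlation; 8 genes over the list alone). In the diabetes comparison neither urothelium (−1.08, adjusted p = 0.403) nor inner medulla markers (−0.95, 0.403) passed. With both scores as covariates 52 genes passed under LXA4 in diabetic mice and 19 in the LXA4 interaction, against 56 and 39 without them. Over the 39 interaction genes 0.839 of the mean change was left (95% interval 0.642 to 1.04).

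Brown fat markers also differed between libraries of the same group. Ucp1, the uncoupling protein of brown fat, reached 122.5 CPM in nondiabetic benzo-LXA4 replicate 1, the library that held most of the Kcnk3, Thrsp, Fasn and Mrap of its group. The brown fat list had a median log2 change of 4.94 with benzo-LXA4 in nondiabetic mice (adjusted p = 9.79e-04, and 0.565 with an estimated correlation; 10 genes over the list alone) and of −2.33 with benzo-LXA4 in diabetic mice (0.00176, and 0.937 with an estimated correlation). It did not pass in the diabetes comparison (0.37, 0.666), and neither did ribosomal and small structural RNA genes (−0.57, 0.666).

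The p53 targets were higher in treated diabetic mice too, against the same nondiabetic vehicle libraries as in the diabetes comparison. The 28 targets outside the leading genes had a median log2 change of 0.34 with LXA4 (adjusted p = 5.89e-05 with an estimated correlation; 9 risen and 2 fallen over all genes). With benzo-LXA4 it was 0.21 (0.00117 with an estimated correlation; 5 risen and 1 fallen). The 12 targets picked from the leading diabetes genes had medians of 1.05 and 1.08, which carry no test, since they were picked for a change against these vehicle libraries.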
